A study of Gallus gallus with 9 samples.

How the data were processed

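Total RNA from 9 cell preparations of the gonad of chicken embryos at 6.5 days was hybridised to the Affymetrix GeneChip Chicken Genome Array, with 1 array per preparation. Per the labels, the cells had been parted by magnetic-activated cell sorting (MACS) into a PGC fraction (3 arrays) and a GSC fraction (6 arrays). PGC is the usual short form for primordial germ cells, and GSC is not spelled out in the labels. The antigen used for sorting and the embryonic sex are not given in the sources used here. Nothing in the labels says whether replicates came from separate pools of embryos, so p-values measure only the spread between these preparations, which may be technical. RNA was extracted with TRIzol and a silica column, and biotin-labelled from oligo(dT)-primed cDNA, per the labels' protocols.

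The deposited values were 1 log2 expression value per probe set and array, which the authors made with RMA, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of each probe set. Its version is not given in the sources used here. The log2 scale is not stated beside the values and was taken from their range, which a 16-bit scanner gives on that scale. RMA gives low probe sets a compressed range, so fold changes of dim genes are understated, and no detection calls were used here. Array medians lay between 3.03 and 3.12. The 57 RPTR reporter probe sets, which match no chicken gene, had a median of 1.60 and a 95th percentile of 2.88. The mean of 46.6% of the tested probe sets lay below that percentile, called the reporter mark here. Where the dimmer group of a gene had arrays below the mark, a fold is given as at least the fold of the brighter group's mean over the dimmer group's mean with such arrays set at the mark, a rule made after the data had been seen. Of the 108 called genes chosen for naming, 14 had a mean below the mark in the dimmer group, and for 1 the mean of the brighter group lay below it too. Log2 changes are the fitted ones. Some arrays of the dimmer group were below the mark for SALL4, ASZ1 and HORMAD1 (1 of 6 each), APOB and FGB (3 of 6 each), KITLG, SYCE3 and CP (1 of 3 each) and PTPRC, WNT11, TGFBR3 and FADD (2 of 3 each), so that their fitted changes are no exact sizes. For arrays, the number of arrays limits the precision.

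The array held 38535 probe sets. The 96 control probe sets whose names begin with AFFX were left out of the tests, and 38439 were tested. Gene symbols came from the platform annotation, which listed 1 symbol for 27168 probe sets, several for 177 and none for 11094. Probe sets with several symbols were not named. Of the probe sets with 1 symbol, 26853 had an Entrez identifier in a RefSeq gene table of assembly GRCg7b, which was used for names only, and 0 symbols changed through it. No coordinates are reported, because the values are given by probe set. The probe set with the highest mean over the 9 arrays stood for its gene, which gave 13009 genes, of which 7334 had more than 1 probe set. Of the 109 genes chosen for naming, 66 were called and had more than 1 probe set, and for 0 of these 66 was another probe set called in the opposite direction. Some of them had other probe sets that were not called, such as SLC27A2 and NCALD (1 of 2 called each), FADD (1 of 3), MDM2 (1 of 4) and CD74 (1 of 3).

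Each probe set or gene was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on cell fraction alone, over all 9 arrays, two-sided. P-values were adjusted by the method of Benjamini and Hochberg over all 38439 probe sets or all 13009 genes, and called at an adjusted p under 0.05. Standard errors are limma's moderated ones. The 23 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists, and again with the correlation estimated from the data. The rotation test fry was also run. Of 726 list symbols, 619 matched a measured gene, 21 of them through a synonym. Among these were SLC2A14 (written as SLC2A3) and ALAS1 (ALAS2), which can stand for a related gene. HSD3B1 was listed under its own symbol, and the listed HSD3B2 led to it as well. The lists share members, with 28 genes in over 1 list. Control probe sets were compared by an exact permutation test over the 84 ways to choose 3 of 9 arrays, two-sided, where the smallest p is 0.0119. That test covered a family of 5 comparisons, adjusted together.

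The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took 13 fixed genes, the 10 genes with the largest rise and the 10 with the largest fall among called genes without overlap of the arrays (placeholder names were only counted), and up to 4 called members of each list with the largest change. Of the fixed genes, NANOG, POU5F3 and WT1 are not listed by the annotation, and no value is given for them. Genes named outside the rule are list members used to describe a list, or are said to have been chosen after their values were seen. A proximal tubule list and a liver plasma protein list, and a test of gene symbol stems, were added after the data had been seen.

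The alternatives were quantile normalization over the 9 arrays, centring of each array on its median, leaving out dim probe sets, eBayes with trend and robust settings, array weights, the replicate number as a block, GSC replicates 1 to 3 only, GSC replicates 4 to 6 only, the mean of a gene's probe sets, an adjusted p under 0.01, an estimated correlation, and leaving out each array in turn. On simulated data for PGC against GSC with 13009 genes, the fit recovered 33.6% of the genes changed by 0.5 on the log2 scale, 83.6% at 1, 98% at 2 and 100% at 3. False calls made up 4.83% of the calls. Each of these runs changed 200 genes and gave both groups the same spread. In the real data limma called 42.0% of the genes, and the spread could differ between groups, as for GATA4 (SD 1.44 in PGC, 0.14 in GSC). The simulated rates therefore do not carry over to the real data. In those simulations, whose genes varied independently, camera found 20 of 20 shifted lists and called 0.236% of the others. The real arrays behaved otherwise: when the 6 GSC arrays were divided 3 against 3 in all 10 ways, with no PGC array in the fit, camera at the preset correlation called between 0 and 7 of the 23 lists (median 1.5), while limma called 0 genes (136 to 1381 at an unadjusted p under 0.05) and camera with an estimated correlation called 0 lists (at most 2 at an unadjusted p under 0.05).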

Results

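Gene expression was measured in cell fractions sorted from the chicken embryonic gonad at 6.5 days, and the stated purpose was to compare PGC with GSC preparations. There were 3 PGC and 6 GSC arrays, and their number limits the precision of every value. Correlations over all probe sets were 0.987 to 0.996 among GSC arrays and 0.974 to 0.990 among PGC arrays, and 0.930 to 0.969 between the fractions. PGC replicate 3 stood nearer the GSC arrays (r 0.956 to 0.969) than PGC replicates 1 and 2 did (r 0.930 to 0.950), and the first principal component, with 72.1% of the variance, placed it between them. On the second component, with 10.3% of the variance, PGC replicate 3 stood apart at 54.99, against -26.65 to 10.17 for the other arrays. No arrays were identical.

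Germ cell markers were higher in the PGC fraction in 19 of 23 measured members, and gonadal somatic cell markers were lower in 19 of 31. DDX4, the germ cell RNA helicase also called VASA, measured 9.09 ± 0.63 (log2, SD, n = 3) in PGC and 4.59 ± 0.19 (n = 6) in GSC, a 22.5-fold difference with a log2 fold change of 4.49 ± 0.22 (SE, limma adjusted p = 2.668e-07). DAZL, a germ cell RNA-binding protein, was 15.1-fold higher (log2 fold change 3.92 ± 0.20 SE). KIT, the stem cell factor receptor, rose by 4.17 ± 0.24 on the log2 scale, PIWIL1, a piRNA-binding protein, by 2.90 ± 0.16 (7.46-fold), and CXCR4, a chemokine receptor below the reporter mark of 2.88 in all 6 GSC arrays, was at least 4.54-fold higher. In the other direction GATA4, a transcription factor of gonadal somatic cells below the mark in 1 of the 3 PGC arrays, was at least 5.41-fold lower in PGC (log2 fold change -2.53 ± 0.45, -1.89 without PGC replicate 1 and -3.31 without PGC replicate 3), LHX9 was 4.51-fold lower (-2.17 ± 0.23), NR5A1 2.24-fold lower (-1.16 ± 0.24) and COL1A2 3.46-fold lower (-1.79 ± 0.25). These genes spread more in PGC (SD 1.44, 0.68, 0.71 and 0.75) than in GSC (0.14, 0.13, 0.15 and 0.10), so their SEs are understated. HINTW, a gene of the W chromosome, measured 9.82 ± 0.24 in PGC and 10.16 ± 0.23 in GSC and did not pass (log2 fold change -0.34 ± 0.15, limma adjusted p = 0.101). It belongs to a family of near-identical copies, so its value is uncertain.

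**Figure D1:**
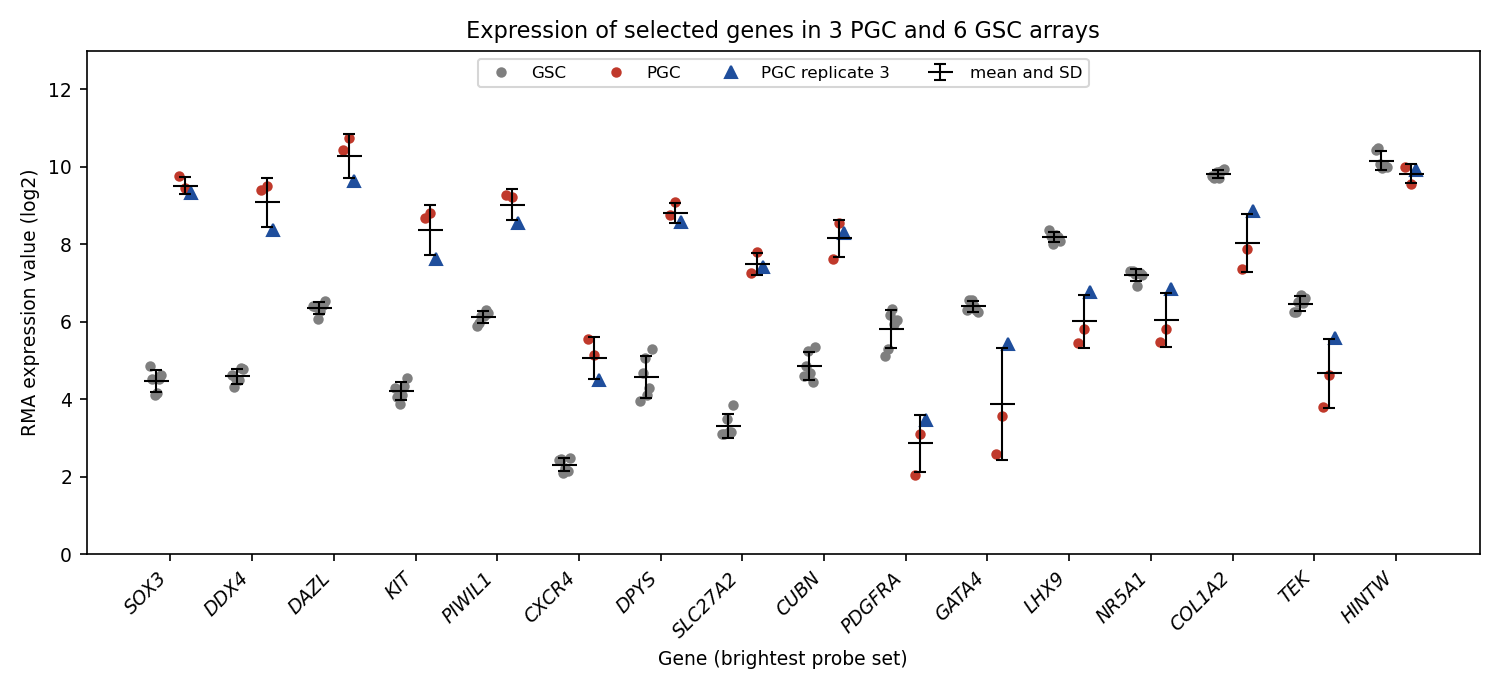
RMA expression value (log2) of 16 genes in each array, with GSC arrays in grey, PGC replicates 1 and 2 in red, PGC replicate 3 as a blue triangle, and the mean and SD of each group in black. DDX4 averages 9.09 in PGC and 4.59 in GSC, and for GATA4 the PGC arrays spread over 1.44 log2 units (SD) below the GSC mean of 6.40.

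Over all probe sets, limma called 5300 higher and 5626 lower in PGC, and 3732 of them changed at least 2-fold (1977 higher, 1755 lower). Over 13009 genes, 2923 were higher and 2543 lower, of which 1047 and 788 changed at least 2-fold. By the fitted values 115 called genes were at least 8-fold higher in PGC (93 with GSC arrays below the reporter mark of 2.88 set at the mark) and 0 were at least 8-fold lower, the fold change of the genes running from -2.95 to 5.05 on the log2 scale around a median of -0.02. The reporter mark limits such folds: the PGC mean of 324 genes called lower and the GSC mean of 539 called higher lay below it, and 1400 genes called lower had a GSC mean at least 8-fold above it. In 36.4% of genes the 3 PGC arrays did not overlap the 6 GSC arrays, where chance gives 2.38%. Of the 57 reporter probe sets, 2 were called. With GSC replicates 1 to 3 only, which leaves fewer arrays, 2966 probe sets were higher and 3038 lower, and 1863 genes were higher and 1531 lower, and with GSC replicates 4 to 6 only 3675 probe sets were lower.

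The 10 genes with the largest fitted rise included some below the mark in GSC, so their order is not read: SOX3, HES5, OTX2, DMRTB1, DDX4, ZIC2, SLC13A3, DPYS, SLC27A2 and VPS29L. SOX3, an HMG-box transcription factor, rose 33.1-fold (9.51 ± 0.22 in PGC against 4.46 ± 0.29 in GSC). HES5, a Notch target, rose 32.1-fold and DMRTB1 26.4-fold, and the transcription factors OTX2 and ZIC2, below the mark in 6 and 4 of the 6 GSC arrays, rose at least 18.35-fold and 18.36-fold. SLC13A3, a dicarboxylate transporter, rose 19.1-fold, DPYS, a pyrimidine-degrading enzyme, 19.0-fold, SLC27A2, a fatty acid transporter, 18.2-fold and VPS29L, below the mark in 3 GSC arrays, at least 16.6-fold. The limma adjusted p of these genes was at most 5.254e-06, which was that of HES5.

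The 10 genes with the largest fitted fall included 7 below the mark in at least 1 of the 3 PGC arrays, and their order is not read either: PDGFRA, RESF1, BMP5, FREM1, ROBO1, FREM2, OGN, GATA4, TRANK1 and NCALD. PDGFRA, a growth factor receptor of mesenchymal cells below the mark in 1 of these arrays, fell at least 6.36-fold (2.86 ± 0.74 in PGC against 5.82 ± 0.50 in GSC, limma adjusted p = 4.994e-05). RESF1 fell 6.97-fold, the basement membrane protein FREM1 and the axon guidance receptor ROBO1 (each below it in 1 array) at least 5.90-fold and 5.37-fold, and BMP5 (in 2 arrays) at least 4.39-fold. FREM2 and the small proteoglycan OGN, below the mark in all 3 PGC arrays, fell at least 4.22-fold and 4.50-fold. TRANK1 fell 5.57-fold and NCALD 5.55-fold. The GATA4 values of PGC replicates 1, 2 and 3 were 2.60, 3.57 and 5.44, against a GSC mean of 6.40.

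**Figure D2:**
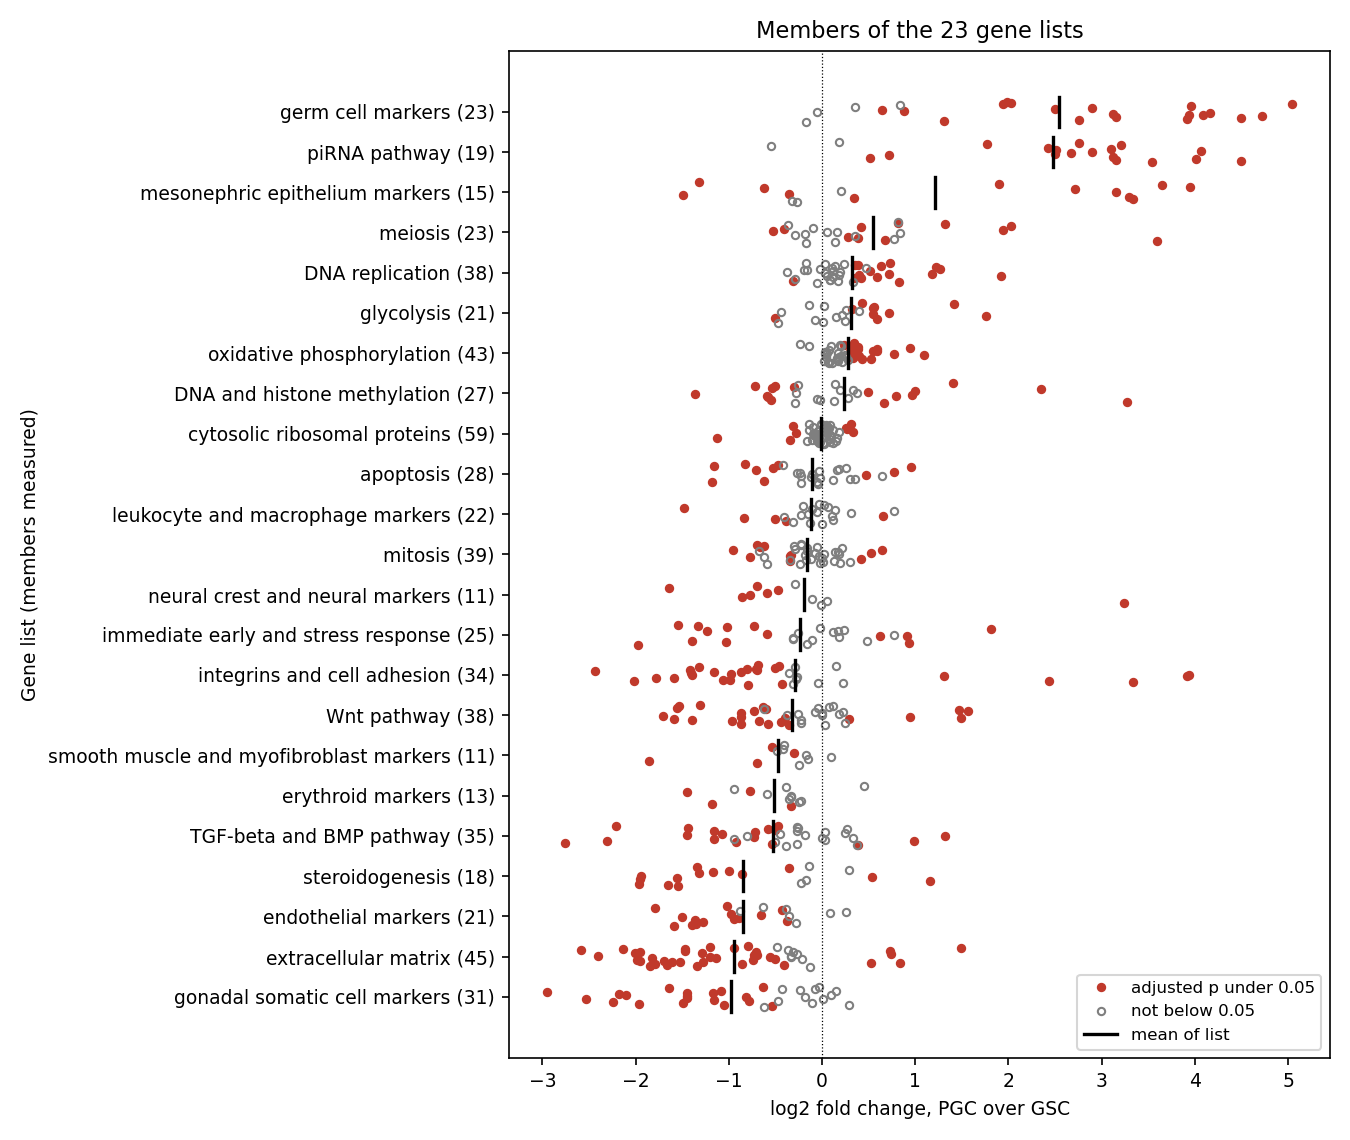
Log2 fold change (PGC over GSC) of every measured member of the 23 gene lists, with called members filled, the others open, and a bar at the mean of each list. The germ cell markers average 2.55 and the piRNA pathway 2.48, and the gonadal somatic cell markers average -0.98.

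Of 23 gene lists, camera at the preset correlation called 16, of which 7 were higher and 9 lower in PGC, fry called 20, and with an estimated correlation camera called 0, the smallest adjusted p being 0.272 (2 with an unadjusted p under 0.05). In 15 of the 16 called lists the means of all 3 PGC arrays lay beyond those of every GSC array, and in the erythroid list those of 2 did. The same preset test called up to 7 lists when the 6 GSC arrays alone were divided 3 against 3. In an exact permutation test chosen after the data had been seen, the mean change of 15 of these 16 lists had an adjusted p of 0.0171 over the 84 splits of the arrays, and the erythroid list 0.0548. The uncalled lists of DNA and histone methylation (0.0171) and of leukocytes (0.0483) also lay under 0.05 there. That test does not compare a list with other genes.

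Of the 23 measured germ cell markers, 19 rose, 0 fell and 4 did not pass (21 and 0 adjusted over the list alone). Their mean log2 fold change was 2.55 (limma's camera, adjusted p = 2.470e-13, and adjusted p = 0.272 with an estimated correlation), and the list mean of all 3 PGC arrays lay above every GSC array. Beside the genes above, DND1 rose by 4.08, SALL4, a zinc finger factor of pluripotent cells, by 3.96 and the surface glycoprotein EPCAM by 3.94. KLF4 (-0.05), BRDT (-0.18) and PRDM1 (0.36) did not pass. Of 19 genes of the piRNA pathway, which silences transposons in the germ line, 17 rose and 0 fell (17 and 1 adjusted over the list alone, and 1 fell without PGC replicate 2), with a mean of 2.48 (adjusted p = 1.698e-10, and adjusted p = 0.414 with an estimated correlation). PNLDC1, which trims piRNA ends, rose by 4.07 ± 0.16 (SE), FKBP6 by 4.02, ASZ1 by 3.54 and TDRD5, below the mark in all 6 GSC arrays, at least 5.93-fold.

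Of 23 meiosis genes, 9 rose and 2 fell (13 and 3 adjusted over the list alone), with a mean of 0.55 (camera adjusted p = 0.0453, and adjusted p = 0.456 with an estimated correlation). HORMAD1 rose by 3.59. SYCP3, a synaptonemal complex protein, STRA8, which is needed for meiotic entry, and TEX12 were below the mark in all 6 GSC arrays and rose at least 2.07-fold, 1.54-fold and 1.08-fold, and STRA8 and TEX12 were each below it in 1 PGC array as well. The 2 that fell were STAG3, a cohesin subunit, by 0.52 and SYCE3 by 0.41, and without PGC replicate 2 SYCE3 (-0.32) lost its call and 1 fell. The recombination genes SPO11 (0.16) and DMC1 (0.13) and the synaptonemal gene SYCP1 (-0.10) did not pass. The list call was lost without GSC replicate 1 (adjusted p = 0.0562), GSC replicate 6 (0.0532), PGC replicate 1 (0.071) or PGC replicate 2 (0.1002), and with dim probe sets left out (0.861), in a range of 0.0091 to 0.861 over all alternatives.

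Gonadal somatic cell markers fell in 19 of 31 measured members and rose in 0 (20 and 0 adjusted over the list alone), with a mean of -0.98 (camera adjusted p = 3.867e-06, and adjusted p = 0.426 with an estimated correlation). Beside PDGFRA, GATA4 and LHX9, ESR1, the oestrogen receptor, fell by 2.25 ± 0.16 (SE). The stem cell factor gene KITLG, whose product binds KIT, fell by 2.10, the aromatase gene CYP19A1 by 1.96 and FOXL2, a factor of the ovary, by 0.79, a call lost without PGC replicate 1 (-0.60) or PGC replicate 2 (-0.54). SOX9 (-0.43), AMH (-0.62) and DMRT1 (-0.11) did not pass. Of 18 steroidogenesis genes, 12 fell and 2 rose (12 and 2 adjusted over the list alone), with a mean of -0.84 (adjusted p = 0.0041, and adjusted p = 0.456 with an estimated correlation). FSHR fell by 1.95, HSD3B1 by 1.94 (-1.34 without PGC replicate 1) and CYP17A1 by 1.65 (-2.25 without PGC replicate 3). FDX1, an electron donor to steroid hydroxylases, rose by 1.15 and HSD17B4 by 0.53, a call lost without PGC replicate 2 (0.36).

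Extracellular matrix genes fell in 32 of 45 members and rose in 5 (35 and 5 adjusted over the list alone), with a mean of -0.94 (camera adjusted p = 5.497e-08, and adjusted p = 0.426 with an estimated correlation). Beside OGN, the laminin LAMA4 fell by 2.41, POSTN by 2.13 and LUM by 2.01. The 5 that rose were the metalloproteinase inhibitor TIMP2 (1.49), the basement membrane collagens COL4A1 (0.83) and COL4A2 (0.52), NID1 (0.73) and LOXL1 (0.74). Of 34 integrins and adhesion genes, 21 fell and 5 rose (21 and 5 adjusted over the list alone), with a mean of -0.29 (adjusted p = 0.001, and adjusted p = 0.414 with an estimated correlation). ITGA8 fell by 2.44 ± 0.30 (SE) and the mesenchymal cadherin CDH11 by 2.02. The members that rose were the epithelial genes EPCAM (3.94), CLDN1 (3.92), CDH1 (3.34) and CLDN3 (at least 1.35-fold, below the mark in all 6 GSC arrays and 1 PGC array), and CDH13 (2.44).

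Endothelial markers fell in 14 of 21 members and rose in 0 (16 and 0 adjusted over the list alone), with a mean of -0.85 (camera adjusted p = 1.207e-04, and adjusted p = 0.456 with an estimated correlation). TEK, an endothelial receptor kinase, fell by 1.79 and FLI1, a transcription factor of endothelial cells, by 1.36. Of 13 erythroid markers, 4 fell and 0 rose (2 and 0 adjusted over the list alone), with a mean of -0.51 (adjusted p = 0.0125, and adjusted p = 0.494 with an estimated correlation). HEMGN, which is also in the gonadal somatic cell list, fell by 1.45 and EPB42 by 1.18, and the globin HBA1 (-0.22) did not pass. The other 2 were RHAG (-0.77, and -0.41 without PGC replicate 1) and ALAS1 (-0.33, and -0.29 without PGC replicate 1), the latter matched only through a synonym to the listed erythroid gene ALAS2. Both lost their call without GSC replicate 1, 2 or 6 or PGC replicate 1 or 2, and RHAG also without GSC replicate 4 or 5. Of 11 smooth muscle and myofibroblast markers, 4 fell and 0 rose (6 and 0 adjusted over the list alone), with a mean of -0.47 (adjusted p = 0.0192, and adjusted p = 0.456 with an estimated correlation). CALD1 fell by 1.86, and ACTA2 (-0.24) did not pass. Without PGC replicate 3, 10 erythroid and 9 smooth muscle markers fell, and without PGC replicate 1 or 2, 2 of each fell. Without GSC replicate 1, 2 or 6, 2 erythroid markers fell, and without GSC replicate 1, 1 rose.

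Leukocyte and macrophage markers were not called as a list (22 measured, 4 lower, 1 higher, and 2 and 1 adjusted over the list alone, mean -0.12, camera adjusted p = 0.291). PTPRC, the pan-leukocyte antigen, fell by 1.49 and CSF1R by 0.84, and CYBB rose by 0.65. Neural crest and neural markers were not called either (11 measured, 6 lower, 1 higher, and 6 and 1 adjusted over the list alone, mean -0.20, camera adjusted p = 0.162). STMN2 fell by 1.65 (-2.31 without PGC replicate 3) and the neuronal RNA-binding protein gene ELAVL4 rose by 3.24 ± 0.17 (SE). Without PGC replicate 3 the neural list mean was -0.42 (adjusted p = 0.0149, range 0.0149 to 0.504 over all alternatives). Without that array 7 leukocyte markers fell, and without GSC replicate 1, 2, 3 or 6 or PGC replicate 1 or 2 that number was 2. Without GSC replicate 1, 2 leukocyte markers rose. The number of neural markers that fell was 2 without PGC replicate 1 and 3 without PGC replicate 2.

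Of 15 measured mesonephric epithelium markers, 8 rose, 4 fell and 3 did not pass (8 and 5 adjusted over the list alone), with a mean of 1.21 and a median of 0.35 (camera adjusted p = 0.0202, and adjusted p = 0.456 with an estimated correlation). The transporter SLC3A1 (3.65), the endocytic receptors CUBN (3.29) and LRP2 (2.72) and the cadherin CDH1 (3.34) rose. The transporter SLC34A2 and the transcription factor HNF4A, below the mark in 5 and 6 of the 6 GSC arrays, rose at least 14.1-fold and 6.18-fold. UMOD, a gene of distal tubules, fell by 1.32, EMX2, which is also in the gonadal somatic cell list, by 1.49 and PAX2 by 0.62, and the fourth was GATA3, which was below the mark in all 9 arrays. Without PGC replicate 3 the mean was 1.14 and the list lost its call (adjusted p = 0.105, range 0.0078 to 0.456 over all alternatives). Without GSC replicate 1, 2 or 6, or PGC replicate 1 or 2, 2 members fell and PAX2 lost its call (-0.54 without PGC replicate 2).

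Of 38 Wnt pathway genes, 18 fell, 5 rose and 15 did not pass (19 and 5 adjusted over the list alone), with a mean of -0.32 (camera adjusted p = 0.0127, and adjusted p = 0.414 with an estimated correlation). LEF1 fell by 1.71 ± 0.09 (SE), FZD4 by 1.59 and WNT11 by 1.55, whereas RSPO3 rose by 1.57 and FZD5, below the mark in all 6 GSC arrays, at least 1.80-fold. Of 35 genes of the TGF-beta and BMP pathway, 15 fell, 3 rose and 17 did not pass (16 and 3 adjusted over the list alone), with a mean of -0.53 (adjusted p = 0.004, and adjusted p = 0.456 with an estimated correlation). Beside BMP5, BMPR2 fell by 2.31 and TGFBR3 by 2.21, and ID4 rose by 1.32.

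Of 43 oxidative phosphorylation genes, 19 rose, 0 fell and 24 did not pass (22 and 0 adjusted over the list alone, and 1 fell without PGC replicate 3), with a mean of 0.28 (camera adjusted p = 3.550e-04, and adjusted p = 0.456 with an estimated correlation). The complex I genes NDUFA5 (1.09 ± 0.12 SE), NDUFS4 (0.95) and NDUFA8 (0.77) were among those that rose. Of 21 glycolysis genes, 9 rose and 1 fell (11 and 2 adjusted over the list alone), with a mean of 0.31 (adjusted p = 0.0287, and adjusted p = 0.456 with an estimated correlation). LDHA, a lactate dehydrogenase, rose by 1.76 and the glucose transporter SLC2A14 by 1.42, and the hexokinase HK1 fell by 0.51, a call lost without PGC replicate 2 (-0.40). The glycolysis call was lost without PGC replicate 1 (adjusted p = 0.0501) or PGC replicate 3 (0.105) and with dim probe sets left out (0.0548), in a range of 0.0105 to 0.456 over all alternatives. Without GSC replicate 5, PGC replicate 1 or PGC replicate 3, 2 members fell, and without PGC replicate 2, 0 fell.

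Of 38 DNA replication genes, 15 rose and 1 fell (15 and 1 adjusted over the list alone), with a mean of 0.32 (camera adjusted p = 0.0138, and adjusted p = 0.494 with an estimated correlation). The origin recognition genes ORC2 (1.92 ± 0.24 SE) and ORC6 (1.18) and the clamp loader gene RFC3 (1.22) rose, GINS3 fell by 0.31, and PCNA (0.03) did not pass. Without PGC replicate 1, 7 members rose. Without PGC replicate 3, 3 members fell, and without GSC replicate 2, 5 or 6 or PGC replicate 1 or 2, 0 fell (GINS3 was -0.27 without PGC replicate 1). The mitosis list was not called (39 measured, 3 higher, 8 lower, and 2 and 5 adjusted over the list alone, mean -0.16, adjusted p = 0.131), and NDC80 fell by 0.96 and TOP2A by 0.70. Without PGC replicate 1 the mitosis mean was -0.24 (adjusted p = 0.031, range 0.031 to 0.647 over all alternatives), and 1 member rose against 7 without PGC replicate 3. Without GSC replicate 2, 4, 5 or 6, 5 mitosis genes fell.

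The DNA and histone methylation list was not called (27 measured, 8 higher, 8 lower, and 8 and 8 adjusted over the list alone, mean 0.24, camera adjusted p = 0.528), and its members went both ways. DNMT3B, a de novo DNA methyltransferase, was 9.68-fold higher in PGC (10.49 ± 0.18 against 7.22 ± 0.32). SUV39H2, a histone H3 lysine 9 methyltransferase, rose by 2.35 and WDR77 by 1.41, whereas the histone demethylase gene KDM6A fell by 1.36 and TET1 by 0.72. Without PGC replicate 1 or PGC replicate 2, 3 members of the list fell, and without GSC replicate 4, 5 fell.

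Immediate early and stress genes were not called as a list (25 measured, 4 higher, 9 lower, and 5 and 9 adjusted over the list alone, mean -0.23, camera adjusted p = 0.321). ATF3 fell by 1.98, MYC by 1.54 and EGR1 by 1.39, and the chaperone gene HSPH1 rose by 1.81. Apoptosis genes were not called either (28 measured, 3 higher, 7 lower, and 3 and 6 adjusted over the list alone, mean -0.11, adjusted p = 0.321). BCL2 fell by 1.18 and FADD by 1.16, and DIABLO rose by 0.96. Without PGC replicate 1 or 2, 4 apoptosis genes fell, and without GSC replicate 1 or PGC replicate 3, 5 rose. Cytosolic ribosomal protein genes had a mean of -0.01 and a median of 0.01 (59 measured, 4 higher, 4 lower, and 0 and 1 adjusted over the list alone, adjusted p = 0.926), camera giving a lower and fry a higher direction. The sign of that mean changed with quantile normalization or with centring of the arrays. Without PGC replicate 1, 1 ribosomal gene rose and 1 fell, and without PGC replicate 2, 1 rose.

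Of the 108 called genes chosen for naming, 14 lost their call when 1 array was left out, and the fold of 5 more moved by over 1.5 times without a PGC array. These 5 were GATA4, HSD3B1, CYP17A1 and STMN2, given above, and the endothelial cadherin CDH5 (-1.59, and -0.97 without PGC replicate 1).

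**Figure D3:**
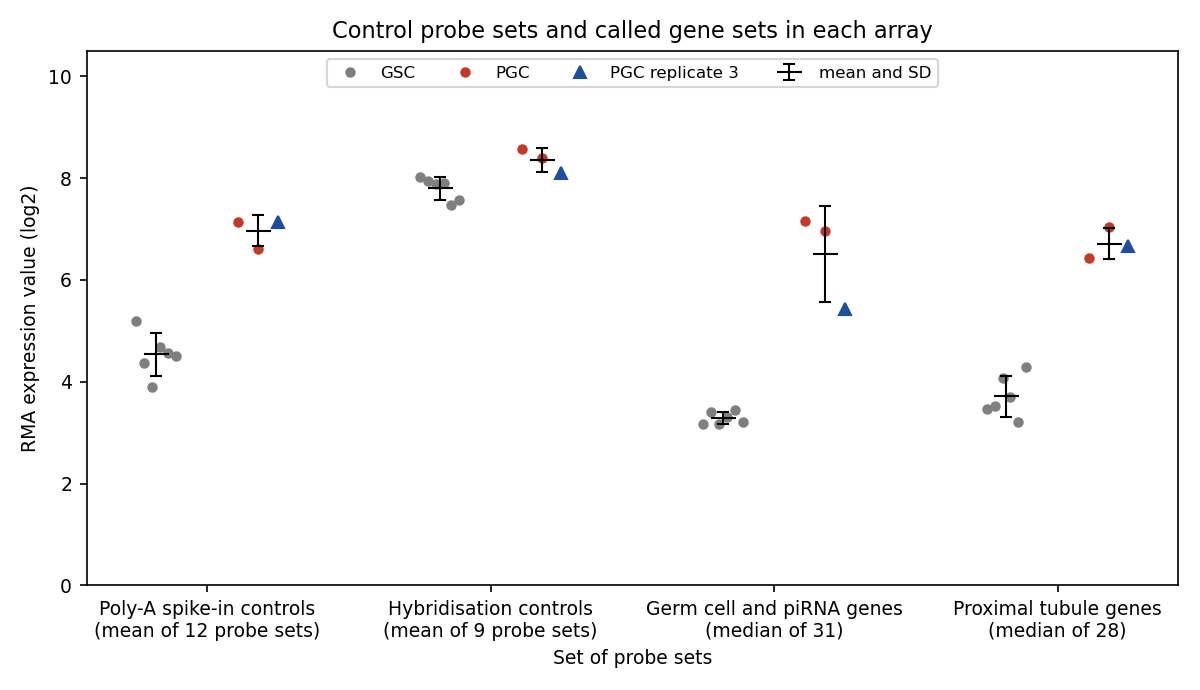
RMA expression value (log2) per array of the poly-A spike-in and hybridisation controls (means of 12 and 9 probe sets) and of 31 germ cell and piRNA genes and 28 proximal tubule genes that rose (medians), with GSC in grey, PGC in red, PGC replicate 3 as a blue triangle, and the mean and SD of each group in black. The poly-A controls average 6.96 in PGC and 4.54 in GSC, and the germ cell median of PGC replicate 3 is 5.43.

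Of 5 comparisons of control probe sets between the fractions, 3 passed. The poly-A spike-in controls, bacterial transcripts added before labelling, measured 6.96 ± 0.30 (SD, n = 3) in PGC and 4.54 ± 0.42 (n = 6) in GSC (exact permutation p = 0.0119, the smallest possible, adjusted p = 0.0198). The hybridisation controls differed less (8.35 ± 0.24 against 7.80 ± 0.23, exact permutation p = 0.0119, adjusted p = 0.0198). The difference between the 3' and 5' actin probe sets, a measure of transcript length after labelling, was 0.77 ± 0.23 in PGC and 0.26 ± 0.08 in GSC (exact permutation p = 0.0119, adjusted p = 0.0198). That of GAPDH was -0.05 in both (exact p = 0.917) and that of EF1A 0.45 and 0.43 (exact p = 0.5), so of the 3 length measures actin alone passed.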

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

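All tests of explanations in this part were chosen after the values had been seen, apart from the counts over the 84 splits of all arrays, which were planned. The 84 splits of the 9 arrays into 3 and 6 tested whether a chance division gives as much. For the 5300 probe sets higher, the 5626 lower and the 3732 changed at least 2-fold, 1 split, the real one, gave a result as large. The same held for the 2923 genes higher and the 2543 lower, and the highest count of the others was 0 in each case. The share of 0.0119 is the smallest that 84 splits can give. Every other split mixes PGC and GSC arrays within a group, which widens the spread there, so counts near 0 were likely beforehand. The splits also cannot part the fractions from a batch that follows them. For the 16 lists called by camera at the preset correlation, 2 of 84 splits gave as many, and the highest of the others was also 16, with GSC replicate 2 and PGC replicates 1 and 2 as the group of 3. That share is under 0.05. The other splits still hold the difference between the fractions, so their counts do not measure how many lists are called without one. The 6 GSC arrays alone, divided 3 against 3 and so with fewer arrays, gave 0 to 7 lists (median 1.5).

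PGC replicate 3 lay nearer the GSC arrays than the other PGC arrays did. That it was a GSC array under a PGC label is argued against by germ cell genes: 26 of the 27 that set PGC replicates 1 and 2 apart lay above every GSC array. An array compressed as a whole, as the one difference, would give all genes a like share. Proximal tubule genes kept 101% of their log2 difference and germ cell genes 77.5%, a gap of 23.6 points (95% interval over resampled genes 16.9 to 46.3). Cells of the GSC kind in that preparation stay no more than a candidate explanation for the germ cell and somatic genes. The fitted share of GSC-type RNA was 50.6% (95% interval 41.8 to 69.5) from the former and 45.6% (30.9 to 54.6) from the latter. The interval of their difference of 5.03 points (-8.28 to 27.8) is too wide to show that the shares are alike. That fit takes PGC replicates 1 and 2 as free of such cells. Such cells as the one difference would give tubule genes a like share, but theirs differed from that of germ cell genes by -54.1 points (-73.9 to -37.3). All these intervals resampled genes, and tubule genes vary together, so the spread between preparations is left out. The tubule list was also written after the data had been seen, so its intervals are no independent test. From PGC replicate 1 to 2 the tubule genes that rose had already shifted by 0.65 and the germ cell genes by -0.16. This 1 array therefore cannot decide on compression, or on such cells, as the one difference. No other biological explanation was tested.

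Proximal tubule genes rose in the PGC arrays, in 28 of 40 members of a list written after the data had been seen, 5 of which are also in the mesonephric list and 3 among the 10 largest fitted rises. Whether germ cells carry these transcripts in a fixed ratio to their own markers cannot be decided here. The log2 ratio of the tubule to the germ cell excess over the GSC mean was -0.77, 0.09 and 0.67 in PGC replicates 1, 2 and 3, a range of 1.44. Of 10000 random near-equal divisions of the germ cell genes, 0 reached that range (95th percentile 0.67). But piRNA genes against germ cell markers, both germ cell sets, had a range of 1.09, also past that percentile. Random divisions are thus too narrow a reference for 2 different gene sets, and there are 3 preparations. Tubule cells of the mesonephros, which adjoins the gonad, in a proportion of their own, and germ cells whose expression of these genes varied between preparations cannot be told apart. The antigen of the magnetic sort is not given, so whether the sort would keep or remove tubule cells is not known. Over the 6 GSC arrays the median tubule deviation had an SD of 0.25, against a median of 0.04 in matched random lists, of which 0% of 10000 reached it, but any genes that vary together would exceed such lists, and an earlier form on GSC replicate 6 alone (0.37), picked for its high tubule genes, was circular. SLC22A5 measured 9.69 in PGC and 8.65 in GSC, FBP1 8.93 and 6.76, and DPYS 8.81 and 4.57, levels of different probe sets that are not ranked.

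The poly-A spike-in controls, which no comparison of genes uses, were 2.42 higher in PGC, the hybridisation controls 0.55 higher, and the actin difference 0.51 higher. Scaling of whole arrays is argued against, because the excess of the poly-A over the hybridisation controls was at least 1.48 in each PGC array. Less sample messenger RNA per spike-in in the PGC labelling reactions may be the cause, since the 4 transcripts rose by 2.20 to 2.63, a range of 0.43. Labelling of the fractions in separate batches cannot be told apart from the fractions, as the labels name a batch or date for 0 arrays. No biological explanation was tested.

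Among 137 groups of 6 GSC values, 6 had an array far from the others, and chance gives about 1 in 20, or 6.85. KDR was 6.52 in GSC replicate 1, against 5.59 to 5.92 in the others, and NR5A1 was 6.93 in GSC replicate 4, against 7.20 to 7.32. RSPO3 was 4.24 in GSC replicate 3, against 4.91 to 5.27, and the mean of the Wnt pathway list was 5.16 in GSC replicate 1, against 4.99 to 5.06. PRIM2 was 3.51 in GSC replicate 3, against 4.43 to 4.82, and its rise in PGC (1.26) lost its call without PGC replicate 1 (1.01) or PGC replicate 2 (0.92), and was 1.86 without PGC replicate 3. RHAG was 6.07 in GSC replicate 1, against 5.26 to 5.55. Its fall in PGC kept its call without GSC replicate 3 or PGC replicate 3 (-1.16) and lost it without any other single array, with -0.41 without PGC replicate 1.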

How the results depend on the processing

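Quantile normalization, centring, and eBayes with trend and robust settings kept every count within 1.5 times and every list on its side of the threshold, apart from the sign of the uncalled ribosomal list. Genes called both as deposited and under another setting that refits the genes kept their direction, except 6 with the mean of probe sets. With the replicate block 3073 probe sets were higher and 2517 lower, and 1845 genes higher and 1287 lower, and 3116 of its 3132 called genes were also called without it. That fit has fewer residual degrees of freedom. Replicate numbers 4 to 6 occur only in GSC, so the block in effect compares replicates 1 to 3 of each fraction as pairs. Its log2 changes are those of GSC replicates 1 to 3 only, so these settings are not separate checks of them. Whether the replicate numbers pair the samples stays open, as the labels do not say. Same-number correlations were 0.19, -0.07 and 0.01. PGC replicate 1 correlated best with GSC replicate 1, but PGC replicate 2 did so with GSC replicate 3 (0.20). So few arrays cannot settle it. GSC replicates 1 to 3 only gave 2966 and 3038 probe sets and 1863 and 1531 genes, GSC replicates 4 to 6 only gave 3675 probe sets lower, and an adjusted p under 0.01 gave 3602 lower. An estimated correlation ended all 16 list calls and left the means as they were: germ cell 2.55, piRNA 2.48, mesonephric 1.21, meiosis 0.55, DNA replication 0.32, glycolysis 0.31, oxidative phosphorylation 0.28, integrins -0.29, Wnt -0.32, smooth muscle -0.47, erythroid -0.51, TGF-beta and BMP -0.53, steroidogenesis -0.84, endothelial -0.85, matrix -0.94 and gonadal somatic -0.98. Meiosis lost its call with dim probe sets left out (0.43), the block (0.56) and GSC replicates 4 to 6 only (0.54), and glycolysis with dim probe sets left out (0.31), array weights (0.29), the block (0.24) and GSC replicates 1 to 3 only (0.24). Array weights, which gave PGC replicate 3 a weight of 0.199, ended the mesonephric call (1.18) and called the neural list (-0.36), and GSC replicates 4 to 6 only ended the erythroid call (-0.40). The ribosomal mean turned positive with quantile normalization (0.0063), centring (0.0115), the block (0.0045), GSC replicates 1 to 3 only (0.0045) and the mean of probe sets (0.0027). The cause was not tested. With 1 array left out, probe sets higher ran from 3944 (without PGC replicate 1) to 6268 (without PGC replicate 3), lower from 4061 to 6669, genes higher from 2298 to 3321 and lower from 1914 to 2983. List means then ran from 0.45 to 0.71 for meiosis, 1.14 to 1.33 for mesonephric, 0.28 to 0.36 for glycolysis, -0.42 to -0.0686 for neural and -0.24 to -0.054 for mitosis markers. Of the results for named genes, 1843 kept their call or lack of one, 115 lost significance and 0 reversed. Probe sets near the reporter level of 2.88 carry little signal, which limits calls of dim genes.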

Other observations

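All tests in this part were chosen after the data had been seen. Genes of the HOX clusters, which pattern the body axis, were lower in PGC in 13 of 29 measured members and higher in 3, and with quantile normalization or centring 12 were lower and 3 higher. HOXA4 fell by 1.79 ± 0.22 (SE, limma adjusted p = 8.264e-05) and HOXA6 by 1.74, whereas HOXD8 and HOXD4, below the reporter mark in all 6 GSC arrays, rose at least 4.70-fold (limma adjusted p = 3.426e-07 for HOXD8) and 3.22-fold. HOXD10, the other that rose, had a PGC mean of 2.51, below the mark as well. Among 158 symbol stems with at least 10 genes, camera at the preset correlation called COL (42 genes, 22 lower, 3 higher, adjusted p = 0.0243), HOXA (11 genes, an antisense gene included, 8 lower, 0 higher, adjusted p = 0.0284) and DENND (13 genes, 9 lower, 0 higher, adjusted p = 0.0345). With an estimated correlation the adjusted p was 0.895 for each. The IFT stem, genes of intraflagellar transport in cilia, had 7 of 14 genes higher and 0 lower (adjusted p = 0.0747, and adjusted p = 0.895 with an estimated correlation). IFT22 rose by 1.82 ± 0.17 (SE) and IFT80 by 1.49.

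The proximal tubule list had 40 measured members, of which 28 rose and 2 fell, with a median of 1.85. Its members were picked after the data had been seen, so no p-value for the change of the list is given. The comparisons above that use these genes have the same limit. By the fitted values 14 were at least 8-fold higher in PGC, and 13 with GSC arrays below the reporter mark set at the mark, HNF4A being the other (at least 6.18-fold). GATM, an enzyme of creatine synthesis, rose by 4.15 ± 0.37 (SE), CLDN10 by 4.07, ASS1 by 3.81 and the amino acid transporter SLC6A19 by 3.68. The 2 that fell were DAB2, by 1.30, and MME, by 0.64 (a call lost without PGC replicate 1, -0.35), and with quantile normalization or centring 29 rose. The liver plasma protein list had 24 measured members, of which 12 rose and 2 fell, with a median of 0.54, and no test of it is given for the same reason. TTR rose by 3.90, APOB by 3.51 and FGB by 3.26, whereas HPX fell by 1.47 (-2.06 without PGC replicate 3) and CP by 1.44. ALB (2.86 in PGC, 2.65 in GSC) and AFP (1.68 and 1.83), 2 of the most abundant liver transcripts, were dim in both fractions.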
